A study of Toxocara canis with 2 samples.

How the data were processed

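Polyadenylated RNA from the whole body of an adult male and an adult female Toxocara canis, the roundworm of dogs, was sequenced as 1 library per sex. Per the labels' protocols, total RNA was extracted with Trizol, fragmented, copied into cDNA from random primers, size-selected on a gel and amplified by PCR. The reads were assembled into unigenes, which stand for assembled transcripts; contigs of related sequence share a cluster name (CL) and a contig number. The assembler, aligner, counting program, their versions and any genome build are not given in the sources used here.

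Per the file headers, the authors deposited raw fragment counts per unigene, the unigene length and FPKM values (fragments scaled to unigene length in kilobases and to the library total) for each library. The deposited counts sum to 18.4 M fragments in the male library and 19.8 M in the female library, the totals stated in the headers. The deposited FPKM values equal the fragment count divided by the unigene length and the library total, with a largest difference of 5.0e-05, so they carry no scaling beyond the library total. Each library's table lists unigenes with at least 1 fragment, and a unigene missing from it was taken as 0 fragments. A further deposited table holds the authors' own comparison of 21280 unigenes, with a log2 ratio of female over male FPKM in which the authors replaced an FPKM of 0 by 0.001. That deposited table also gives a p-value and a false discovery rate per unigene; every unigene in it has a deposited FDR under 0.001 and a log2 ratio of at least 1 in size, and the test behind the p-value is not named in the headers. The annotation (best protein hits in Nr and Swiss-Prot, COG, KEGG and GO) comes from the same table, so a unigene outside the authors' calls carries no name here.

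With 1 library per sex there is no replicate, so no test was run and no p-value was computed. Before the data were examined, a size rule was fixed: at least 5 FPKM in the higher library and at least 2 in size for log2((female FPKM + 1)/(male FPKM + 1)), which is a 4-fold difference on a scale that understates the change of low unigenes. Fold differences of named unigenes are ratios of library shares without the pseudocount, with an exact 95% binomial (Clopper-Pearson) interval from the fragment counts. Where a library held 0 fragments, the fold is a lower bound set against 3 fragments per library. Intervals and bounds cover counting error only, and neither the variation between worms nor that between library preparations.

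The names of genes to report were set by a rule fixed before the data were examined. It took the 12 unigenes per direction with the largest log2 ratio among those that passed the size rule and had an informative protein description, 1 per identical description, and the 5 most abundant described unigenes of each library. Per gene list it also took up to 3 members with the highest mean FPKM and the outermost member in each direction. The rule named 109 unigenes, and the text describes part of them. A name states the best database match, which for repetitive sequences can be weak.

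The 23 gene lists were fixed beforehand as search patterns: major sperm protein, kinases and phosphatases of nematode testis, vitellogenin, eggshell and chitin, oocyte and embryo regulators, cell cycle, meiosis and small RNA, histones, cuticle, muscle, nerve, intestine, protease inhibitors, excretory-secretory proteins, body fluid and lipid binding, ribosomal proteins, respiratory chain, glycolysis and malate fermentation, heat shock and stress, sex determination, microtubules, dog and bacteria. They were matched to the Nr and Swiss-Prot descriptions with organism names removed, because a pattern otherwise matched parts of species names; the dog and bacteria lists were matched to the Nr organism. The lists hold unigenes of the authors' table only. Each list is given by the median log2 ratio of members with a mean of at least 1 FPKM, an order-statistic 95% interval that describes the spread among members, the median with 0 counts set to 3 fragments and no pseudocount, and the percentile of its median among 10000 random lists of the same size matched on mean FPKM in 20 bins. The random lists were drawn from 6259 described unigenes of the authors' table with a mean of at least 1 FPKM. Of these, 56.5% were higher in the female library, and their median log2 ratio was 0.93.

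The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated counts for 70267 unigenes with the depth of each library and 1 level per unigene, pooled over both libraries. The changed unigenes were drawn from those with a pooled level of at least 5 FPKM, so recovery of lower unigenes was not tested. With 200 unigenes changed 8-fold, 99% were recovered, and with 200 changed 32-fold, 100%. In both simulations 0 had the wrong direction and 0 unchanged unigenes were called, and the intervals covered 96.9% and 97.0% of the true ratios. The simulated counts held counting noise only. They do not show how many calls differences between worms or library preparations would cause. Of 40 random lists of 40 unigenes, 2 lay above the 95th percentile without a shift and 40 after a shift of 4 on the log2 scale.

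Unigenes with at least 5 FPKM in both libraries numbered 9842, and their median log2 ratio of female over male was 0.31, a shift of 1.24-fold. Values are given on the deposited scale, and ratios near this shift lie near the centre of the shared unigenes. The alternatives tried were other pseudocounts (0.1 and 5), scaling to the median ratio, to a trimmed mean and to totals without the 50 most abundant unigenes, other floors and fold limits, a minimum length of 500 bases, annotated unigenes alone, and other ways to form and summarise the lists. No genome position is reported, since the files identify unigenes by number; the reference gene table of the T. canis assembly Toxocara_canis_adult_r1.0 was not used, because unigene numbers match none of its identifiers. Some descriptions (19 unigenes) are not reported here.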

Results

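The transcriptomes of an individual adult male and an individual adult female Toxocara canis were compared, with 1 whole-body library of each sex. The male library held 18.4 M fragments on 64618 unigenes and the female library 19.8 M fragments on 58435 unigenes. Of 70267 unigenes seen in either library, 52786 were seen in both, 11832 in the male library only and 5649 in the female library only. A count of 3 fragments, the bound used for a count of 0, corresponds on a unigene of 1 kilobase to 0.163 FPKM in the male and 0.152 FPKM in the female library. It corresponds to more on shorter unigenes, and the median length was 543 bases. No replicate exists, so every difference below is between these libraries and has no replicate check.

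The comparison of the sexes addressed which genes are transcribed differently between male and female adult worms. Sperm proteins on the male side and yolk and eggshell proteins on the female side were among the largest named differences. Major sperm protein isoform beta (CL2081.Contig1), the protein whose filaments drive the crawling of nematode sperm, stood at 32102 FPKM in the male and 7.50 FPKM in the female library, a 4281-fold difference (95% interval 3382 to 5502). Vitellogenin (Unigene14425), the yolk protein precursor, stood at 0.286 FPKM in the male and 14049 FPKM in the female library, a 49051-fold difference (34154 to 73241), and alone took 7.75% of the female fragments. By the size rule 3160 unigenes were higher in the male and 1669 in the female library, a male share of 65.4%. This excess held for large differences; at 2-fold the counts were 4104 and 4785. With at least 5 FPKM in the higher library, 1516 unigenes of the male had 0 fragments in the female library, against 230 in the other direction. Some of the 230 had a best hit in Trypanosoma. Without such hits the size rule gave 3156 unigenes higher in the male and 1646 in the female library. Across all unigenes the log2 values of the libraries had a Pearson correlation of 0.59 and a Spearman correlation of 0.38, described without a test because unigenes are not independent replicates.

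Sperm cytoskeleton transcripts were higher in the male library nearly throughout. Of 79 unigenes in the major sperm protein list, 76 were higher in the male library and 67 passed the size rule there, while 0 passed it in the female direction. The list median was -5.00 (-5.54 to -4.08), or -6.90 with 0 counts at their bound, below all 10000 random lists (percentile 0). Its unigenes took 3.960% (Clopper-Pearson 3.952 to 3.969%) of male fragments and 0.0166% (0.0160 to 0.0171%) of female fragments. MFP2b (Unigene7412), a fiber protein of Ascaris sperm, was 10947-fold higher in the male library (6401 to 20560), at 5436 against 0.497 FPKM. MFP3 (Unigene28938) was at 4203 against 0.381 FPKM, where the female value rests on 2 fragments and the ratio was 11018 (3050 to 90986). MFP1-alpha (Unigene30674) and MSP-domain protein 5 (Unigene30675) had 0 female fragments and were at least 6296-fold and at least 9964-fold higher in the male library. MSP-domain protein 4 (Unigene6928) was 809-fold higher (670 to 986). The outermost member in the other direction, a Mospd2 protein (Unigene11245) with a motile sperm domain, was 4.14-fold higher in the female library (3.77 to 4.56).

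Kinases and phosphatases of the types expanded in nematode testis went the same way. Of 135 members, 123 were higher in the male library, 82 of them by the size rule, and the median was -3.44 (-4.05 to -2.68; -6.08 with 0 counts at their bound; percentile 0). With no filter on low values it was -1.64. A tau-tubulin kinase match named P34 (Unigene14055) was at 1054 FPKM in the male and 4.82 FPKM in the female library, 219-fold higher (180 to 269). A catalytic subunit of protein phosphatase 1 (Unigene30680) was at 888 against 0.0428 FPKM, the latter from 1 fragment, a ratio of 20762 (3726 to 820080). A further phosphatase 1 unigene (Unigene27471) had 0 female fragments and was at least 1983-fold higher in the male library. The argonaute ALG-4, of the protein family that binds small RNAs, had 3 unigenes, all higher in the male library. Unigene7227 was 89.6-fold (75.3 to 107), Unigene287 117-fold (86.8 to 161) and Unigene17494 30.4-fold higher (12.7 to 95). They made up the meiosis and small RNA list, whose median of -5.81 (-6.49 without the pseudocount) lay at percentile 16.1 of lists of 3. When any annotation column was matched, the median of this list was 1.18, in the other direction.

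**Figure D1:**
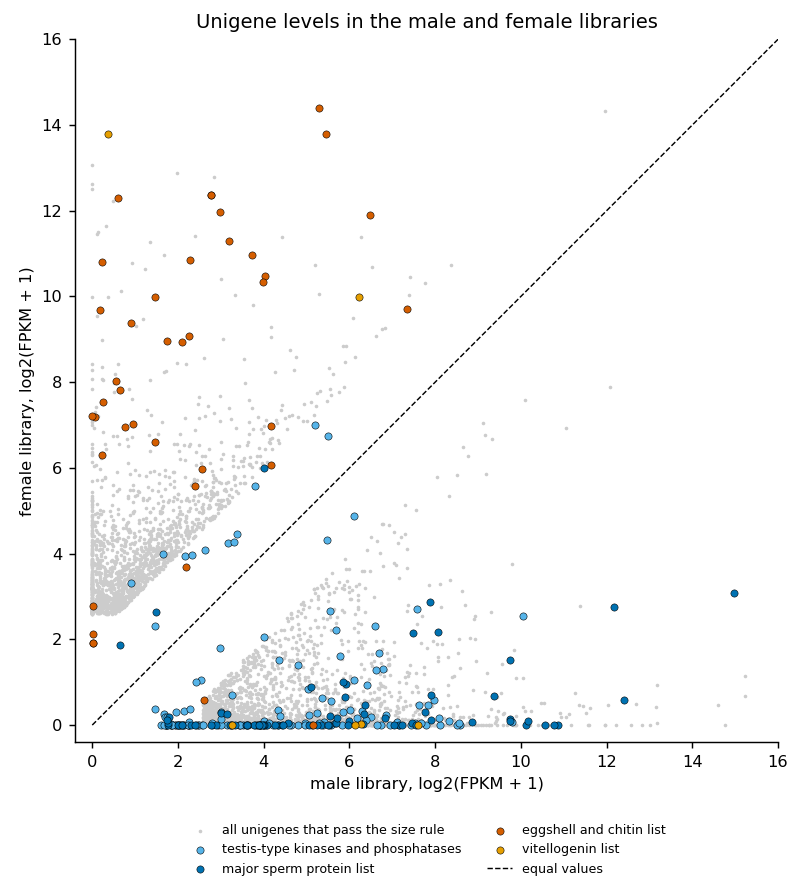
Levels of unigenes in the male (x axis) and female (y axis) library as log2(FPKM + 1). Grey points are the 4829 unigenes that pass the size rule and coloured points the members of 4 gene lists; 76 of 79 major sperm protein members lie on the male side and 38 of 40 eggshell and chitin members on the female side of the dashed line of equal values.

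In the eggshell and chitin list 38 of 40 members were higher in the female library, 33 by the size rule, with a median of 6.83 (5.42 to 7.28; 8.17 with 0 counts at their bound; percentile 100). Its unigenes took 9.25% (Clopper-Pearson 9.24 to 9.27%) of female fragments and 0.0686% (0.0674 to 0.0698%) of male fragments. Much of this came from transcripts described as immunosuppressive ovarian message protein of Ascaris with Swiss-Prot matches to chondroitin proteoglycans, which are eggshell components in nematodes. CL957.Contig5 was at 38.3 FPKM in the male and 21442 FPKM in the female library, 560-fold higher (527 to 596). Unigene1613 was 330-fold higher (307 to 355), and Unigene3521, the outermost member, was 9508-fold higher in the female library (5666 to 17391). The outermost male member, CL5996.Contig5, matched a Swiss-Prot eggshell protein but carried an Nr description of a lipase, had 0 female fragments and was at least 143-fold higher in the male library.

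The vitellogenin list held 6 members in opposite directions. Both unigenes whose Nr description was vitellogenin were higher in the female library, Unigene14425 as above and Unigene4105 at 73.6 against 1008 FPKM, 13.7-fold higher (13.4 to 14.0). The other 4 matched a Swiss-Prot vitellogenin-2 and were higher in the male library; Unigene29259 among them, described as GH24453 in Nr, had 0 female fragments and was at least 892-fold higher. The median over the list was -4.69 (-8.31 without the pseudocount, percentile 14.4), or -0.84 with no filter on low values, while the summed FPKM was 425 in the male and 15057 in the female library. Other transcripts among the largest female excesses were the trypsin inhibitor-like SWM-1 (Unigene40009, 1944-fold, 1086 to 3895), a lipase (Unigene16, 1920-fold, 1256 to 3102) and extracellular superoxide dismutase (Unigene41159), which removes superoxide. The last had 2 male fragments and a ratio of 10285 (2847 to 84934). The antimicrobial peptide ASABF-delta (Unigene39800) had 0 male fragments and was at least 842-fold higher in the female library.

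Most members of the oocyte and early embryo list and of the cell cycle list were higher in the female library. Of 27 members of the oocyte and early embryo list, 21 were higher in the female library, with a median of 1.43 (0.98 to 1.98; 2.13 without the pseudocount; percentile 98.1). Abundance did not lean this way. Summed values gave 0.13, and all 37 called members held 30465 male and 15658 female fragments, with 24883 of the male ones on Unigene12894. The list consisted largely of matches to gld-1, a translational repressor of the germline, which went both ways. Unigene12894 was 670-fold higher in the male library (492 to 938), at 243 against 0.363 FPKM. CL964.Contig2 was 7.01-fold (6.27 to 7.86) and CL5901.Contig8 19.4-fold higher (11.7 to 34.3) in the female library. Of 93 cell cycle and replication members 73 were higher in the female library, with a median of 1.09 (0.96 to 1.26; 1.42 without the pseudocount; percentile 86.2). PCNA (Unigene15816), the sliding clamp of DNA polymerase, was 3.30-fold higher in the female library (3.03 to 3.61). A cyclin-dependent kinase 1 match (Unigene18018) was 283-fold higher in the male library (149 to 619). Histones were mixed, with 9 members higher in the male and 13 in the female library and a median of 0.99 (-1.67 to 2.08; 1.53 without the pseudocount; percentile 56.2). Summed values gave -1.46. On the male side, a linker histone H1.6 match (Unigene4614) was at 637 against 167 FPKM (3.81-fold, 3.65 to 3.97), and an H2A match (Unigene27600) had 0 female fragments and was at least 353-fold higher. On the female side 4 of the 22 histones had a best hit in Trypanosoma, and without them the median was -0.09.

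Sex determination genes were few and low. In the list of 6 measured members, 3 were higher in each library, with a median of -0.15 (-4.82 to 1.72; -0.74 without the pseudocount; percentile 32.4). With no filter on low values the median was 0.68, and with any annotation column 1.02. A DM-domain unigene matching mab-3 (CL2133.Contig2), a transcription factor of male differentiation in nematodes, was at 17.8 against 0.384 FPKM, 46.5-fold higher in the male library (29.2 to 78.8). A further DM-domain unigene (CL4948.Contig2) had 0 female fragments and was at least 183-fold higher in the male library. A match to tra-1 (Unigene20774), the terminal regulator of the sex determination pathway in Caenorhabditis elegans, was 2.82-fold higher in the female library (2.49 to 3.19).

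Secreted and surface proteins differed by family. Of 127 excretory-secretory and surface members, 81 were higher in the male library, 37 by the size rule against 13 in the female direction. The median was -1.78 (-2.17 to -1.25; -3.31 without the pseudocount; percentile 0). The C-type lectin Tc-ctl-4 (CL5879.Contig1), from a family of carbohydrate-binding proteins, was at 1937 FPKM in the male and 0.222 FPKM in the female library, 8739-fold higher (4435 to 20243). A further C-type lectin domain unigene (Unigene30177) was at 9213 against 0.0332 FPKM, the latter from 1 fragment, a ratio of 277808 (49861 to 10972882). The outermost female member also had a Swiss-Prot match to a C-type lectin (CL957.Contig7, clec-141) and stood at 2.20 against 1985 FPKM, 904-fold higher in the female library (538 to 1653), under an Nr description of immunosuppressive ovarian message protein. A VAP-1-like secreted protein (Unigene18206) was 17.7-fold higher in the male library (17.0 to 18.4). Protease inhibitors went the other way, with 18 of 25 members higher in the female library and a median of 1.57 (0.78 to 5.25; 2.59 without the pseudocount; percentile 99.6). With 1 unigene per description the median was 3.23, and summed values gave 4.94. Among them, the trypsin inhibitor match Unigene39700 was at 0.259 against 3217 FPKM (12434-fold, 4856 to 45636). A match to serine protease inhibitor 1 (Unigene12252) was at 1.34 against 1583 FPKM (1182-fold, 773 to 1910). A serpin (CL4258.Contig1) was 20.8-fold higher in the male library (15.1 to 29.5).

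In the body fluid and lipid binding list 18 of 20 members were higher in the female library, with a median of 1.61 (1.02 to 2.44; 2.03 without the pseudocount; percentile 99.2). TBA-1 (Unigene8950), the nematode polyprotein allergen that binds fatty acids and retinol, was abundant in both libraries, at 4008 and 20594 FPKM, 5.14-fold higher in the female (5.08 to 5.20). The ABA-1 matches Unigene4744 and Unigene23209 were 3.0-fold (2.90 to 3.11) and 8.02-fold higher (7.69 to 8.38) in the female library. An intracellular globin (Unigene11852), which the list also held, was 2.34-fold higher in the male library (2.29 to 2.40), at 2073 against 885 FPKM.

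Members of the body tissue lists went both ways. Muscle structure had 33 of 52 members higher in the female library and a median of 1.03 (-0.82 to 1.28; 1.20 without the pseudocount; percentile 69.6). Calponins, actin-binding proteins of muscle, went both ways, Unigene7482 at 498 against 240 FPKM (2.07-fold higher in the male, 2.03 to 2.12) and Unigene3949 at 100.5 against 227 FPKM (2.26-fold higher in the female, 2.16 to 2.37). Cuticle and collagen had 18 of 33 members higher in the female library and a median of 1.01 (-1.76 to 1.49; 1.24 without the pseudocount; percentile 70.3). The direction reversed for members with a mean of at least 10 FPKM (-5.66) and for summed values (-2.02). Its most abundant members, such as Unigene10615 at 240 against 0.406 FPKM, had a helicase as Nr description and a vertebrate collagen as Swiss-Prot match. A collagen of the nematode cuticle (Unigene41049) was 100-fold higher in the female library (48.3 to 250).

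Neuronal signalling had 45 of 73 members higher in the female library and a median of 1.21 (-0.93 to 1.57; 1.57 without the pseudocount; percentile 98.9), while summed values gave -0.18. Both synaptobrevins named here, vesicle fusion proteins, were higher in the male library. Unigene8094 was 180-fold higher (76.6 to 554), and Unigene27424 had 2 female fragments and a ratio of 1689 (467 to 13953). A syntaxin match (Unigene40014) was 116-fold higher in the female library (64.8 to 233). Intestine and digestion had 29 of 41 members higher in the female library and a median of 1.15 (0.80 to 1.54; 1.51 without the pseudocount; percentile 92.7). By the size rule 8 were higher in the male and 5 in the female library. Summed values gave 0.34, and no filter on low values 0.30. Trypsin family transcripts again went both ways. Unigene8740 was 5.67-fold higher in the male (5.44 to 5.92) and Unigene42073 1449-fold higher in the female library (665 to 3948). Microtubule genes were higher in the female library for 43 of 58 members, with a median of 1.35 (1.08 to 1.80; 1.91 without the pseudocount; percentile 99.4). The median was 1.25 without the 5 members that had a best hit in Trypanosoma. Alpha tubulin Unigene37612 was 7.64-fold (7.3 to 8.0) and beta tubulin CL3402.Contig3 16.5-fold higher (15.3 to 17.8) in the female library.

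**Figure D2:**
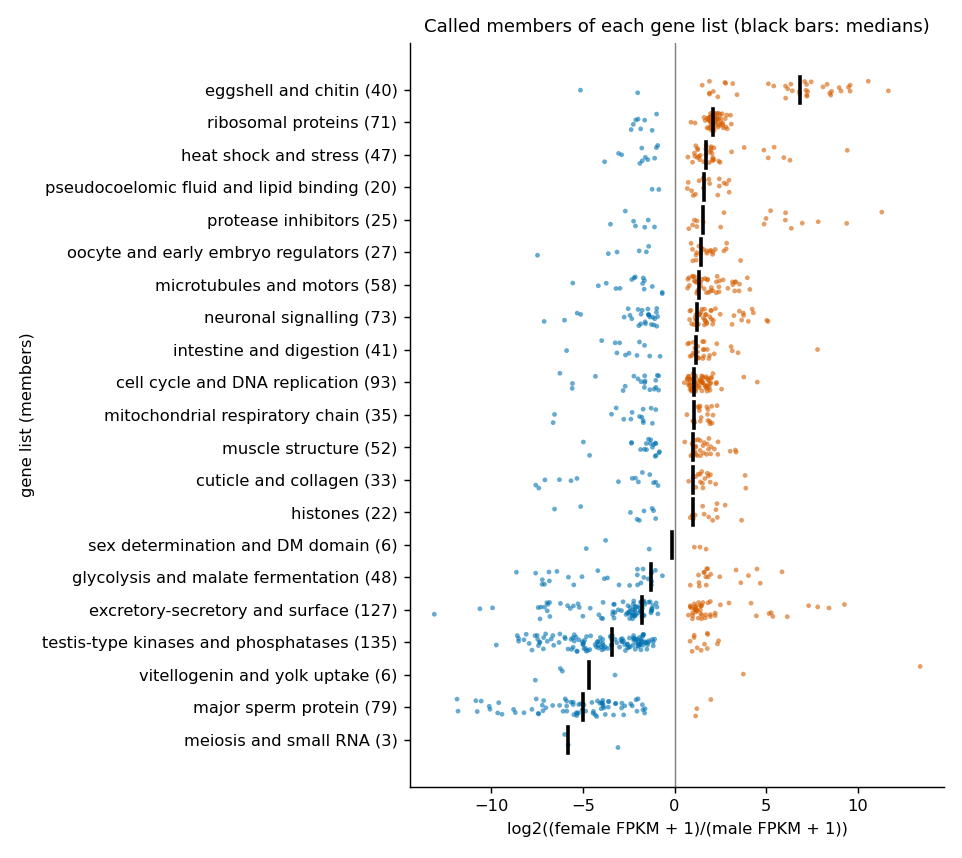
Log2 ratio of female over male FPKM (pseudocount 1, x axis) for the called members of 21 gene lists, blue where higher in the male and orange where higher in the female library, with black bars at list medians and member numbers in brackets. Medians run from -5.81 for the 3 meiosis and small RNA members and -5.00 for major sperm protein to 6.83 for eggshell and chitin; the gap around 0 comes from the 2-fold limit of the authors' table.

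For some energy enzymes, such as phosphoenolpyruvate carboxykinase, different copies were higher in each library. The list for glycolysis and malate fermentation, the anaerobic route of adult ascarids, had 29 of 48 members higher in the male library, 17 by the size rule against 6 in the female direction. Of the 48, 14 had no metabolic enzyme as KEGG name, such as protein kinases, and 12 of the 14 were higher in the male library. The 34 metabolic enzymes were split 17 to 17 with a median of -0.093, and 12 to 6 by the size rule. Of the 17 higher in the female library, 2 matches to glyceraldehyde-3-phosphate dehydrogenase (Unigene39321 and Unigene39687) had a best hit in Trypanosoma and 0 male fragments. The median over all 48 was -1.27 (-2.03 to 1.33; -2.76 without the pseudocount; percentile 11.3), and -1.36 without the 2 Trypanosoma hits. Phosphoenolpyruvate carboxykinase, which fixes carbon dioxide onto phosphoenolpyruvate in that route, had 7 unigenes, 4 higher in the male and 3 in the female library. Unigene26609 was at 397 FPKM in the male with 0 female fragments, at least 8902-fold higher, while CL1305.Contig2 was 134-fold higher in the female library (94 to 199), at 0.756 against 102 FPKM. Propionyl-CoA carboxylase beta chain had 3 of 4 unigenes higher in the male library, and the copy with the highest mean over both libraries, Unigene18370, was 2.53-fold higher in the female (2.46 to 2.60). An aldolase (Unigene1530) and a glyceraldehyde-3-phosphate dehydrogenase (CL4806.Contig2) were 2.07-fold (2.03 to 2.11) and 2.38-fold higher (2.31 to 2.46) in the male library. Respiratory chain members were split 15 to 20, with a median of 1.06 (-1.70 to 1.41; 1.07 without the pseudocount; percentile 90.4), while summed values gave -0.87. Of the 35, 13 had a best hit in a nematode, and 10 of these were higher in the female library (median 1.1). These 10 include a V-type proton ATPase subunit (Unigene6526, 2.59-fold higher, 2.47 to 2.70). It is described as a vacuolar ATP synthase and is not part of the respiratory chain. Best hits in Homo were found for 9 members, all at 0 in the male library with 330 female fragments. Best hits in Cyprinus were found for 4, all at 0 in the female library with 493 male fragments, and best hits in Bigelowiella for 3, also at 0 there. The mitochondrial NADH dehydrogenase subunit 4L (Unigene12223) was 2.43-fold higher in the male library (2.39 to 2.48).

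**Figure D3:**
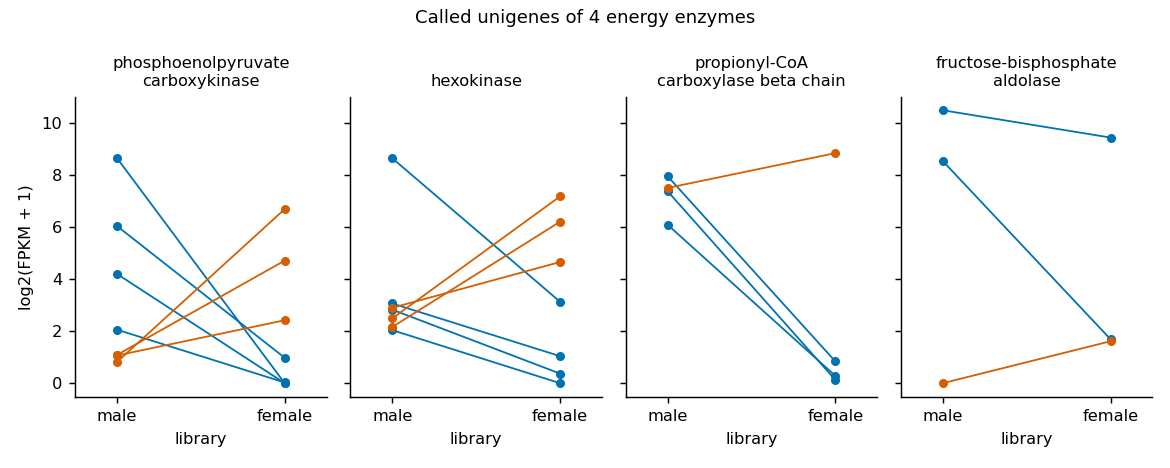
Levels of the called unigenes of 4 energy enzymes as log2(FPKM + 1) in the male and female library, with a line per unigene, blue where higher in the male and orange where higher in the female. Unigenes of phosphoenolpyruvate carboxykinase divide 4 to 3 and those of hexokinase 4 to 3 between the libraries.

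Stress genes were higher in the female library for 36 of 47 members, with a median of 1.71 (1.24 to 2.0; 2.21 without the pseudocount; percentile 100). The median was 1.30 without the 9 members whose best hit was in Trypanosoma. Small heat shock protein OV25-1 (Unigene2149), a chaperone, was 35.1-fold higher in the female library (32.9 to 37.5), at 75.6 against 2656 FPKM. A heat shock protein 70 (CL1466.Contig3) was 2.77-fold higher in the male library (2.68 to 2.86). Ribosomal proteins had 63 of 71 members higher in the female library and a median of 2.10 (2.01 to 2.23; 2.77 without the pseudocount; percentile 100), but 60 of the 71 had a best hit in Trypanosoma. The remaining 11 had a median of -1.63, with 3 higher in the female library. Among them 40S ribosomal protein S2 (Unigene1751) was 2.36-fold higher in the male library (2.24 to 2.48). The dog list held 3 members with a median of -1.26 (-1.28 without the pseudocount, percentile 45.2). A keratin (Unigene11860) among them was 74.0-fold higher in the male library (55.5 to 101). The bacteria list held 0 members.

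Higher values in the male library were listed for 11845 unigenes in the authors' deposited table, and higher values in the female library for 9435. The authors' deposited table held every unigene that passed the size rule, and 12038 of its 21280 unigenes were under 5 FPKM in the higher library. The p-values behind it compare these libraries, not the sexes, since each sex is represented by 1 worm. Contigs of a cluster can be fragments or variants of the same transcript, so a count of unigenes is not a count of genes.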

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

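The tests in this part were chosen after the result was seen. A set of unigenes had their best match in trypanosomes and fragments in the female library alone. Of 119 called unigenes with a best Nr hit in Trypanosoma, 109 were higher in the female library, with 3737 female fragments and 0 male fragments, above the 3 fragments that a count of 0 allows. The ribosomal list, matched to Nr and Swiss-Prot descriptions, held 60 of the 109. By words in the Nr description alone, the 109 included 56 ribosomal proteins (1512 fragments), 5 tubulins (610) and 4 histones (220). They also included 2 procyclins (117), which are surface proteins of the insect stage of the parasite, and the kinetoplastid protein KMP-11 (53). Variant surface glycoproteins, the coat of the bloodstream stage, were named by 0 of them. The other 10 were higher in the male library, with 8450 male and 45 female fragments, so a best hit in Trypanosoma also occurred on sequence of the male library.

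Worm transcripts that matched a trypanosome by chance are argued against as the source of the 109 as a set. For each of them, the 20 female-higher unigenes with a nematode best hit and the nearest number of female fragments were taken, and 36.6% of these were at 0 in the male library. The share among the 109 was 63.4 percentage points higher. RNA of another organism in the female library stays open. Best hits in other kinetoplastid genera were expected to be at 0 in the male library as well, and 0 of 22 were, which is 0% (Clopper-Pearson 0 to 15.4%); the fragments on them numbered 21228 in the male and 5067 in the female library. A further unigene (Unigene42925), whose description names Leishmania without an organism entry, was not among the 22 and had 0 male and 27 female fragments. The expectation failed for these genera. They lie outside the set of 109, and transcripts of a Trypanosoma need not have best hits in them, so the test supports no source and leaves a Trypanosoma open. The tables do not show where such RNA would have come from, and a difference between the sexes was not tested, as each is 1 worm.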

How the results depend on the processing

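The settings chosen after the data were seen were those without Trypanosoma best hits, with contigs summed by cluster, with the female library thinned, with 0 counts at 3 fragments and no pseudocount, with metabolic enzymes alone in the glycolysis list, and with nematode best hits alone in the respiratory chain list. The direction of 109 named unigenes was kept in each of 545 values under other pseudocounts and scalings. This outcome was fixed beforehand and gives no support. A pseudocount cannot change a direction. Each named unigene differed at least 2-fold in the authors' table, and the largest scaling shift was -0.32 on the log2 scale. Of 266 list medians under the alternatives, 189 stayed within the interval of the reported median. A further 63 moved beyond it in the same direction, and 14, in 8 lists, changed sign. None of the sign changes came from a scaling, which could not change the direction of any list member. The number of lists with a median higher in the female library was 14 as reported and 11 to 16 under the alternatives. Unless stated, the cause of a change was not tested. No paired analysis was possible because each sex has 1 library, which also leaves no replicate to leave out.

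Counts by the size rule depended on the limits, and the excess of male unigenes reversed at 2-fold, where 4104 were higher in the male and 4785 in the female library (male share 46.2%, against 65.4% as reported). With a pseudocount of 5 the counts were 1366 male and 512 female, with a floor of 20 FPKM 1269 and 597, and for annotated unigenes 1365 and 753. The female count was 623 at 8-fold (male share 77.2%) and 1092 at 500 bases or longer. The male share was 73.1% after median centring and 73.4% after trimmed mean scaling. Unigenes at 0 in the other library numbered 8625 male and 3769 female at a floor of 1 FPKM, 448 and 48 at 20, and 11832 and 5649 with no floor. The Pearson correlation was 0.25 for unigenes at 5 FPKM in either library and 0.43 with a pseudocount of 0.1, and the Spearman correlation was 0.27 at 5 FPKM. Of the calls in the authors' deposited table, 3160 male and 1669 female passed the size rule, and 5645 female calls had at least a 4-fold difference.

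With a pseudocount of 0.1 list medians were -7.41 for major sperm protein, -5.68 for testis kinases and phosphatases, -7.88 for vitellogenin, 7.30 for eggshell, 2.07 for oocyte regulators, 1.29 for cell cycle, -6.43 for meiosis and small RNA, -3.27 for excretory-secretory proteins, 5.08 for ribosomal proteins, -2.48 for glycolysis, 2.33 for stress and 1.83 for microtubules. With a pseudocount of 5 they were -3.06 for major sperm protein, -1.72 for testis kinases, 5.36 for eggshell, 0.74 for oocyte regulators, 0.68 for cell cycle, 0.53 for intestine, -0.68 for excretory-secretory proteins, 0.73 for ribosomal proteins, 0.72 for stress and 0.80 for microtubules; sex determination changed sign to 0.015. With 0 counts at 3 fragments they were -6.90, -6.08, -8.31, 8.17, 2.13, 1.42 and -6.49 for the first 7 lists in the order given for 0.1, 1.57 for nerve, -3.31 for excretory-secretory proteins, 2.77 for ribosomal proteins, -2.76 for glycolysis, 2.21 for stress and 1.91 for microtubules.

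Summed values gave -9.04 for major sperm protein, -4.11 for testis kinases, 0.13 for oocyte regulators, 0.66 for cell cycle, -6.17 for meiosis and small RNA, 0.34 for intestine, -1.09 for excretory-secretory proteins and 0.74 for ribosomal proteins. They changed the sign of vitellogenin (5.14), histones (-1.46), cuticle (-2.02), nerve (-0.18) and the respiratory chain (-0.87), since a sum follows the most abundant members. Members with a mean of at least 10 FPKM gave -6.09 for major sperm protein, -5.43 for testis kinases, 1.42 for cell cycle and -1.10 for excretory-secretory proteins, and changed the sign of histones (-1.41), cuticle (-5.66) and ribosomal proteins (-1.10). No filter gave -1.64 for testis kinases, 0.93 for cell cycle, 0.30 for intestine, -1.23 for excretory-secretory proteins, 1.16 for stress and 0.92 for microtubules, and changed the sign of sex determination (0.68). Matching any annotation column gave 0.98 for oocyte regulators and changed the sign of meiosis and small RNA (1.18) and sex determination (1.02). With 1 unigene per description, major sperm protein was at -7.45 and testis kinases at -4.33. Median centring and trimmed mean scaling gave 0.80 and 0.79 for cell cycle, 1.87 and 1.86 for ribosomal proteins, and 1.07 and 1.06 for microtubules; leaving out the 50 most abundant unigenes gave 2.45 for ribosomal proteins. Without Trypanosoma best hits histones (-0.087) and ribosomal proteins (-1.63) changed sign, because members with such hits were higher in the female library.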

Other observations

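The families, the copies of enzymes and the scaling test of the male excess in this part were chosen after the results were seen. The tests with clusters summed and with the female library thinned were added after the data were seen but before their results, and the test of the body tissue lists was written before its result. In the authors' COG and KEGG columns, 73 families had at least 10 members with a mean of at least 1 FPKM. A unigene can be in a family of each column, so the columns are counted apart. Of 38 COG families, 7 had a median below 99% of random lists and 1 above 99%, and of 35 KEGG families 12 and 4. Tau-tubulin kinases were higher in the male library for 71 of 71 members, with a median of -3.92 and summed FPKM of 4294 against 21.4. Protein tyrosine phosphatases of the COG family were higher there for 62 of 71 members (median -3.41) and FER tyrosine kinases for 22 of 23 (-3.21). Matches to the splicing factor CWC22 were higher there for 11 of 11 (-3.71). These 11 had 4 different descriptions, and without 1 member whose best hit was in Trypanosoma the median was -3.87. The cyclophilin family (11 of 11, -2.43, percentile 7.48) and the proteasome regulatory family (11 of 11, -1.72, percentile 2.58) were also higher in the male library throughout, though their medians were less far from random lists. The 13 members of the Puf family of translational repressors in COG were higher in the male library with summed FPKM of 142729 against 33.0, and they include repetitive transcripts whose best hits were in Dictyostelium.

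On the female side, the KEGG chitinase family had 11 of 13 members higher in the female library (median 8.48, percentile 100). These 13 came from 6 assembly clusters with 4 different descriptions, and their overlap with the eggshell and chitin list was not examined. Tubulin alpha had 17 of 22 members higher there (1.92, percentile 100). Without 2 members whose best hit was in Trypanosoma this was 15 of 20 (1.83). Long-chain acyl-CoA synthetases, which activate fatty acids, had 8 of 11 members higher there (1.87, percentile 99.4). Flamingo cadherins had 14 of 14 (1.60, percentile 98.9), SNF2 helicases 13 of 13 (1.45, percentile 97.4) and multidrug ABC transporters 11 of 11 (1.35, percentile 87.8).

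Hexokinase had 7 unigenes that divided between the libraries. Unigene21949 was 51.1-fold higher in the male (46.0 to 56.8), at 396 against 7.75 FPKM, and Unigene11139 was 31.0-fold higher in the female library (25.5 to 37.9), at 4.61 against 143 FPKM. Propionyl-CoA carboxylase beta chain Unigene21653 was 1753-fold higher in the male library (684 to 6435). Of 38 called unigenes with a best hit in Homo, 19 were higher in each library, 14 were at 0 in the male and 14 at 0 in the female library. Of 41 called unigenes with a best hit in Dictyostelium, 38 were higher in the male library, with 775014 male fragments against 3067 female fragments. The most abundant unigene of the male library by fragments, CL2178.Contig4, took 2.94% of them and had 9 female fragments.

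More unigenes were higher in the male than in the female library by the size rule, with a ratio of 1.89. With totals without the 50 most abundant unigenes of each library, the ratio was 1.74 (4005 against 2299). That scaling shifted the female values by only 0.052 on the log2 scale, so it could hardly change the ratio. The scale shifts of median centring (-0.31) and trimmed mean scaling (-0.32) were larger. They raised the male share from 65.4% to 73.1% and 73.4%. For 4-fold differences, these values argue against scaling to totals that a few abundant unigenes dominate as the whole cause. After contigs were summed by cluster and 1 entry was kept per description, the ratio was 1.80. This argues against broken transcripts as the whole cause only where the pieces share a cluster or description. Pieces that share neither were not joined, and 2118 of the 4829 unigenes by the size rule had a protein description. Transcripts broken into such pieces stay open. Thinning the female fragments to the male total gave 1.90. A larger set of male-limited transcripts, for example of the testis, may account for the excess. The sex, the individual worm and the library cannot be separated here, and the excess was absent at a 2-fold limit on the deposited scale.

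The body tissue lists (muscle, intestine, nerve, cuticle and respiratory chain) had medians near a 2-fold excess in the female library. Such a median is not particular to them. The described unigenes from which the random lists were drawn had a median of 0.93, and the medians of these lists lay at percentiles 69.6 to 98.9. Of their 233 members, 211 had at least a 2-fold difference with the pseudocount added. Of these 211, 61.6% were higher in the female library. After the shared unigenes were centred this was 53.2% (99 against 87 members). The test decides nothing about a scale shift, because the members come from the authors' deposited table with its 2-fold limit, so that centring can remove female members just above the limit but cannot add male members missing from that table. Scale, sex and individual worm all stay open.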
